A study of Drosophila melanogaster with 8 samples.

How the data were processed

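The deposited table holds CPM values per gene for 8 libraries, made by the authors from reads aligned with HISAT2 to the dm6 assembly, per the submitters' processing notes. Libraries were made with a stranded total RNA kit (TruSeq), per the labels' protocols. The versions of the aligner and the genome, the read counter, the annotation and the use of strand are not given in the sources used here. Each column of CPM sums to 1000000, and the steps between low values gave whole reads for 100% of the values above 0 (tolerance 0.01), so reads per library were recovered. The table lists 17807 genes, of which 17710 have their gene ID in the reference annotation (Ensembl, BDGP6.54) and 97 do not. The 56 symbols that were missing or had been turned into dates were filled from the gene ID. All 38 genes of the mitochondrial genome were at 0, so that list was not tested. Reads of near-identical paralogs, such as Amy-p and Amy-d or the Hsp70 genes, and of overlapping or antisense genes may be shared or lost in the authors' counting, and their values are uncertain.

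The comparisons, tests, gene lists, named-gene rule and alternatives were fixed before the data were examined, except 1 alternative and the tests said below to be chosen later. Genes with at least 1 CPM in at least 2 libraries were tested, 10575 in all. limma 3.58.1 (R 4.3.3) with a mean-variance trend was fitted to log2(CPM + 1) over all 8 libraries with 3 genotype means, and p-values were adjusted by Benjamini-Hochberg with a threshold of 0.05. A fold change on the log2(CPM + 1) scale understates the change of low genes. The single mutant has 2 libraries and borrows the spread of the other groups. edgeR 4.0.16 (quasi-likelihood, TMM) and DESeq2 1.42.0 on the recovered reads were alternatives, and edgeR and limma shared 5892 calls for the double mutant against Canton-S, 1853 for the single mutant and 3878 between the mutants.

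From general knowledge of fly genes 34 lists were written, with 808 entries, of which 804 were matched (17 by synonym), and 33 lists with at least 3 measured genes were tested with camera at a preset correlation of 0.01. camera with an estimated correlation and fry were alternatives. Other alternatives were pseudocounts of 0.1 and 5 CPM, no filter, a filter at a mean of 5 CPM, median-ratio scaling, quantile normalization, the replicate number as a block, a fit of only the 2 groups compared, limma without the trend, and each library left out in turn. The fit without single mutant replicate 2 and double mutant replicate 3 was added after their values were seen.

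Genes are named by rule. These are the 3 family members, the 8 largest rises and 8 largest falls among genes past the threshold whose groups do not overlap and which reach a mean of 5 CPM in 1 group, the 4 members with the smallest p of each called list and of each list with at least 3 changed genes, the 2 members with the highest mean of each marker list, and the sex and dosage compensation genes. Small and non-coding RNAs were left out of the largest changes, and some of the genes that the rule gives are not printed. In a self-test on simulated counts with 200 changed genes, limma recovered 24%, 50%, 94% and 98% of genes changed 1.5-, 2-, 4- and 8-fold between the double mutant and Canton-S sizes, with 7 unchanged genes among 140 calls. For the single mutant it recovered 16%, 52%, 96% and 98%, with 13 unchanged genes among 144 calls. Between the mutants it recovered 16%, 54%, 86% and 100%, with 16 unchanged genes among 144 calls. The last 2 shares of unchanged genes are above the 5% that the threshold of 0.05 aims at. The 200 genes were split evenly between rises and falls, and were far fewer than the genes called in the data. With fewer changed genes the adjusted threshold is stricter, so these recoveries need not hold for the data. Nor does the self-test examine the scaling to library totals when many genes change.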

Results

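Total RNA was sequenced from the central nervous system (CNS) dissected from larvae of Drosophila melanogaster in the earliest larval stage, L1. There were 3 genotypes. Canton-S, a wild-type laboratory strain, gave 3 libraries. Larvae homozygous for elav5, a deletion allele of elav, gave 2 libraries and are called the single mutant. Larvae with deletions of both elav and fne, named elav5fne here, gave 3 libraries and are called the double mutant. elav, fne and Rbp9 encode the ELAV/Hu family of the fly, RNA-binding proteins that in neurons act on alternative splicing and on the choice of 3' ends. Reads counted in genes came to 31216373, 33030173 and 38056274 in Canton-S replicates 1 to 3, 30038106 and 33400572 in the single mutant, and 32096997, 34846210 and 35693445 in the double mutant. Expression is given as CPM, the reads of a gene scaled to the library total, as mean ± SD over the libraries of a group, and a change as the log2 ratio of CPM + 1 with its standard error (SE). At these depths 3 reads correspond to between 0.0788 and 0.0999 CPM, a floor that covers counting error only. Adjusted p-values are from limma unless another tool is named. The labels do not say whether the libraries of a genotype came from separate sets of animals, so p-values measure only the spread between these samples.

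The transcripts of the targeted genes were examined in each library before any comparison. elav (FBgn0260400, X chromosome, 509235 to 523226 in the Release 6 assembly) stood at 602, 620 and 599 CPM in Canton-S, 33.4 and 24.4 CPM in the single mutant, and 53.2, 61.0 and 53.7 CPM in the double mutant. fne (FBgn0086675, X chromosome, 12917477 to 12950417) stood at 960, 1045 and 1038 CPM in Canton-S, 938 and 1129 CPM in the single mutant, and 141, 179 and 127 CPM in the double mutant. Every library thus followed its label for both genes. The low values left in the mutants are reads counted over the whole gene, and the labels do not give the extent of either deletion. Rbp9 (FBgn0010263, chromosome 2L, 2954762 to 2968434), the member of the family not targeted, stood at 7.57 ± 0.389 CPM in Canton-S (n = 3), 12.1 ± 0.418 in the single mutant (n = 2) and 18.2 ± 9.34 in the double mutant (n = 3).

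**Figure D1:**
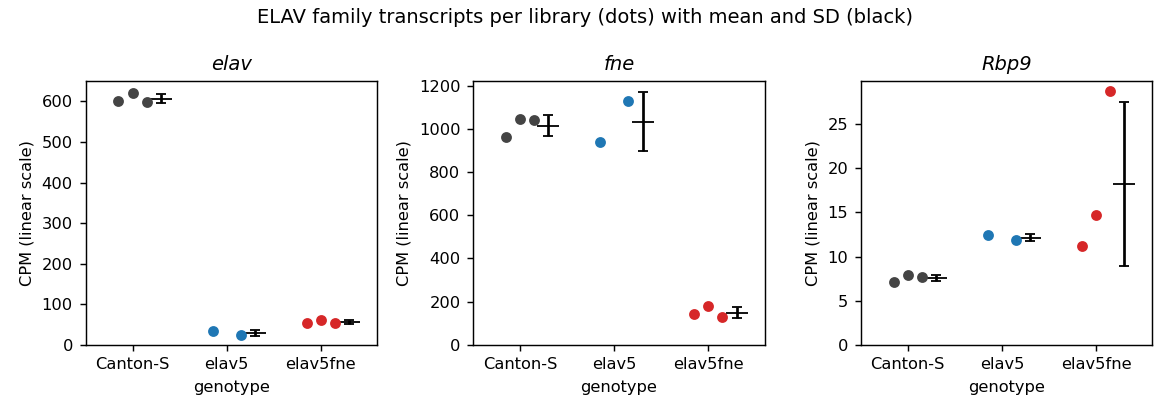
CPM of elav, fne and Rbp9 on linear axes in each library, as dots by genotype, with the mean and SD of each group in black. elav was at most 61.0 CPM in every mutant library and at least 599 CPM in Canton-S, fne was low only in the 3 double mutant libraries, and the 3 double mutant values of Rbp9 spread from 11.2 to 28.8 CPM.

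The first comparison set the double mutant, which lacks both elav and fne, against Canton-S. The mutants and Canton-S are separate lines, and no test here separates the loss of a gene from other differences between lines. Of the 26 measured genes of synaptic vesicle release, 23 fell and none rose. The deepest fall was that of Snap25, a core SNARE of vesicle fusion, at 4.69 ± 4.26 CPM against 251 ± 19.2 CPM in Canton-S (n = 3 each). In the other direction, 21 of 25 neuroblast and progenitor genes rose, among them asense (ase), a proneural-type factor of neuroblasts, at 207 ± 23.3 CPM against 15.8 ± 1.01 CPM. The transcript of fne fell by 2.77 on the log2 scale (SE 0.13, adjusted p = 2.8e-06) and that of elav by 3.42 (SE 0.11, adjusted p = 1.1e-06), while Rbp9 rose by 1.06 (SE 0.29, adjusted p = 0.015).

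Lists of neuronal function were called lower in the double mutant. The synaptic vesicle list had a median log2 change of -0.83, and beside Snap25 it held falls of Syt7, a synaptotagmin, of Rop, the Sec1/Munc18 protein of the fly, of shi, dynamin, and of Syx1A, syntaxin, whose log2 changes were -2.21, -1.51, -1.53 and -1.22. Adjusted over the list alone, 24 of its genes fell. The set test camera gave the list an adjusted p = 7.2e-10, and an adjusted p = 0.41 with an estimated correlation. Of 18 genes for neurotransmitter synthesis and transport, 16 fell and none rose (17 fell adjusted over the list alone, median -1.46). The vesicular GABA transporter VGAT went from 318 ± 18.0 to 37.5 ± 5.69 CPM, the vesicular monoamine transporter Vmat from 1399 ± 37.3 to 196 ± 35.8 CPM, and choline acetyltransferase ChAT from 332 ± 12.9 to 94.5 ± 10.8 CPM. The camera test gave this list an adjusted p = 7.2e-10, and an adjusted p = 0.41 with an estimated correlation. Among 33 neurotransmitter receptors 26 fell and 1 rose (27 and 1 adjusted over the list alone, median -0.65), with falls of the nicotinic subunits nAChRalpha4 (-2.65) and nAChRalpha7 (-2.42) and of the serotonin receptor 5-HT2B (-2.30) on the log2 scale. Of 26 voltage-gated and related ion channels 19 fell and 3 rose (20 and 4 adjusted over the list alone, median -0.84), with falls of the potassium channel genes Shal (-1.91), sei (-1.89) and Shab (-1.87). The receptor and channel lists had adjusted p = 5.7e-08 and 1.8e-06, and adjusted p = 0.45 and 0.41 with an estimated correlation.

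Neuropeptide transcripts showed the lowest median of the neuronal lists, -1.80, with 30 of 33 genes lower and 2 higher, both over all genes and adjusted over the list alone. Ilp2, an insulin-like peptide of brain neurosecretory cells, went from 87.3 ± 7.63 to 1.67 ± 0.771 CPM (log2 change -5.08, SE 0.24). Pdf, the circadian pigment-dispersing factor, went from 43.3 ± 4.33 to 0.570 ± 0.476 CPM (log2 change -4.85, SE 0.23), and Capa, a diuretic peptide precursor, from 54.5 ± 3.47 to 2.57 ± 0.641 CPM. The list had an adjusted p = 5.2e-13 and an adjusted p = 0.36 with an estimated correlation. Of 11 genes for peptide processing and dense-core vesicles 7 fell and 1 rose, the same counts as adjusted over the list alone, with falls of the amidating lyase Pal2 (-1.49) and the prohormone convertase amon (-1.05). That list had an adjusted p = 0.025 and an adjusted p = 0.48 with an estimated correlation.

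Most measured neuroblast genes rose in the double mutant. Beside ase, the proneural genes sc and l(1)sc reached 28.5 ± 0.673 and 19.2 ± 0.895 CPM against 0.556 ± 0.118 and 1.74 ± 0.394 CPM in Canton-S. The neuroblast list had a median of 1.97, 1 member that fell, the same counts adjusted over the list alone, and an adjusted p = 1.5e-07 (adjusted p = 0.41 with an estimated correlation). Of 36 genes of the cell cycle and DNA replication 15 rose and none fell (13 rose adjusted over the list alone, median 0.31). Genes of opposite role were among them, the cyclin-dependent kinase inhibitor dap (log2 change 3.59) and the mitotic phosphatase stg (2.66). The list had an adjusted p = 0.0094 and an adjusted p = 0.55 with an estimated correlation.

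Lists of stress, death and defence were called higher. Of 24 genes of cell death, JNK signalling and injury 22 rose and 2 fell, as they did adjusted over the list alone, with a median of 1.62. The death gene grim reached 35.5 ± 5.98 against 1.13 ± 0.184 CPM, the death gene skl 34.8 ± 6.82 against 2.50 ± 0.808 CPM, and the matrix metalloprotease Mmp1 165 ± 24.0 against 25.1 ± 5.75 CPM. Of 29 detoxification genes 23 rose and 1 fell (24 and 1 adjusted over the list alone, median 1.49), including Cyp6a13, a cytochrome P450 (20.7 ± 1.21 against 0.540 ± 0.0389 CPM), and GstE1, a glutathione transferase (158 ± 21.6 against 10.5 ± 3.54 CPM). These lists had adjusted p = 3.0e-06 and 6.3e-06, and both had an adjusted p = 0.41 with an estimated correlation. Among 15 measured genes of humoral immunity 12 rose and 1 fell (12 and 2 adjusted over the list alone, median 1.81), including the NF-kappaB factor Rel (267 ± 18.2 against 68.7 ± 8.08 CPM). Of 20 heat shock and unfolded protein genes 10 rose and none fell, also adjusted over the list alone (median 1.68), including the endoplasmic reticulum chaperone Hsc70-3 (1072 ± 117 against 372 ± 60.2 CPM). Without single mutant replicate 2 and double mutant replicate 3 together, 16 of them rose, and without Canton-S replicate 1 the median was 0.97. The immunity and heat shock lists had adjusted p = 0.0081 and 0.0043, and adjusted p = 0.51 and 0.55 with an estimated correlation.

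Ribosomal and metabolic lists were called as well. All 42 measured genes of cytoplasmic ribosomal proteins rose, also adjusted over the list alone, by a median of 0.69 on the log2 scale, RpL3 from 1317 ± 35.3 to 2236 ± 78.0 CPM. Of 13 glycolysis genes 12 fell and none rose, also adjusted over the list alone (median -1.47), with Pgi at 538 ± 41.7 against 1631 ± 45.4 CPM and Ldh, lactate dehydrogenase, at 399 ± 48.7 against 1792 ± 80.7 CPM. Of 31 nuclear genes of mitochondrial respiration 21 fell and none rose (23 fell adjusted over the list alone, median -0.34). The ribosomal, glycolysis and respiration lists had adjusted p = 7.2e-10, 2.7e-08 and 4.7e-06, and adjusted p = 0.51, 0.36 and 0.51 with an estimated correlation. Of 18 ecdysone response genes 10 fell and 3 rose, also adjusted over the list alone (median -0.70). The nuclear receptor gene Hr3 fell (1.41 ± 0.247 against 9.54 ± 0.391 CPM) and so did Eip71CD, a methionine sulfoxide reductase gene (11.9 ± 1.05 against 144 ± 33.6 CPM). The list had an adjusted p = 0.0081 and an adjusted p = 0.36 with an estimated correlation.

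Genes tied to the choice of 3' ends were compared as whole genes, since a CPM per gene does not measure which 3' end is used. Of 28 genes reported with neural-extended 3' UTRs, which include elav and fne themselves, 17 fell and 8 rose, also adjusted over the list alone (median -0.36). Ank2, a giant ankyrin of axons, went from 3718 ± 112 to 750 ± 103 CPM, and ewg, a neuronal transcription factor long known as a target of ELAV, from 211 ± 22.3 to 702 ± 30.3 CPM. Of 17 factors of 3' end processing 9 fell and 2 rose, also adjusted over the list alone (median -0.40), with Cpsf6 at 87.8 ± 3.99 against 162 ± 8.17 CPM. Both lists had an adjusted p = 0.023, and adjusted p = 0.61 and 0.41 with an estimated correlation.

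Markers of other tissues were measured beside these lists. Of 20 muscle genes 16 rose and none fell (17 adjusted over the list alone, median 2.03), and their median CPM per library was 47.6, 45.1 and 35.6 in Canton-S, 94.9 and 38.7 in the single mutant and 113, 214 and 471 in the double mutant. Zasp52, a protein of the muscle Z disc, stood at 133 ± 43.4 against 10.1 ± 0.731 CPM, and Mhc, the muscle myosin heavy chain, at 2345 ± 2073 against 428 ± 70.4 CPM (adjusted p = 0.051). Of 15 trachea and cuticle genes 9 rose (11 adjusted over the list alone), and of 25 gut genes 9 rose (5 adjusted over the list alone, median 1.97), none falling in either list. The median CPM of the gut genes was 38.2 in double mutant replicate 3 and between 0.210 and 3.62 in the other 7 libraries. Without that library 15 muscle genes, 6 trachea and cuticle genes and 9 gut genes rose, and the medians were lower, 1.33 for muscle, 0.97 for trachea and cuticle and 1.00 for gut. Without double mutant replicate 1 instead, the gut median was 2.98. Without replicate 3 and single mutant replicate 2, 6 gut genes rose, and the gut call was lost on the same genes (adjusted p = 0.059) but kept after the filter was applied anew (adjusted p = 0.041). Of 10 ring gland genes, markers of the endocrine gland attached to the brain, 6 fell and none rose (7 fell and 1 rose adjusted over the list alone, median -0.75), with spok, a gene of ecdysone synthesis, at 3.43 ± 0.637 against 15.4 ± 4.15 CPM. The muscle, trachea and cuticle, gut and ring gland lists had adjusted p = 0.0010, 0.017, 0.017 and 0.023, and adjusted p = 0.55, 0.55, 0.65 and 0.51 with an estimated correlation.

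The remaining 11 lists were not called in the double mutant. Axon guidance and adhesion genes split evenly, with 16 of 46 higher and 16 lower (16 and 17 adjusted over the list alone, median -0.09, mean 0.10, adjusted p = 0.73). The largest rise among them was that of Nlg1, a neuroligin, at 87.5 ± 0.493 against 4.34 ± 0.877 CPM, while the receptor phosphatase Lar fell to 32.6 ± 2.82 from 94.0 ± 3.40 CPM. Of 25 glial genes 10 rose and 6 fell (10 and 7 adjusted over the list alone, median 0.05, but -0.02 under TMM scaling, adjusted p = 0.81), including a rise of loco and a fall of wrapper (log2 changes 1.03 and -1.48). The neuronal RNA-binding protein list includes elav and fne themselves, and was not tested without them. Of its 25 genes 5 rose and 13 fell (6 and 13 adjusted over the list alone, adjusted p = 0.058), with a rise of how (2.19) and a fall of shep (-1.15). This list was called without any 1 of 4 libraries, the 2 of the single mutant and double mutant replicates 1 and 2 (adjusted p = 0.045, 0.045, 0.049 and 0.033). Of 10 Hox and segment identity genes 5 fell and none rose, also adjusted over the list alone (adjusted p = 0.082), among them Ubx (log2 change -0.88), and the list was called without double mutant replicate 2 (adjusted p = 0.030). The ELAV/Hu family itself, with 1 gene higher and 2 lower, had an adjusted p = 0.082. Sex and dosage compensation genes (4 of 6 higher, 1 lower, and 5 and 1 adjusted over the list alone) had an adjusted p = 0.13. Among tissue markers, 2 of 8 fat body genes rose and 1 fell, 7 of 18 hemocyte genes rose and 2 fell, 6 of 16 eye disc and photoreceptor genes rose and 1 fell, 3 of 7 salivary gland genes rose and 2 fell, and 5 of 8 germline genes rose and 1 fell. These were the same counts as adjusted over the list alone, with adjusted p = 0.88, 0.51, 0.24, 0.72 and 0.12.

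Across all 10575 genes tested, 6259 passed the test between the double mutant and Canton-S, 3435 higher and 2824 lower, and 1681 of the former and 662 of the latter changed at least 2-fold. edgeR on the recovered reads called 6404 genes and DESeq2 6620. camera with an estimated correlation called 0 of the 33 lists in each of the 3 comparisons. Each list call by camera thus rests on the preset correlation of 0.01. fry, which presets no correlation, called 26, 12 and 16 lists in the 3 comparisons. It asks whether the genes of a list changed at all, not whether they changed more than other genes. The largest rises by the fixed rule, beside 3 genes known by CG numbers and CG34105, were those of w, the transporter of eye pigment precursors whose mini-white form marks many transgenes (639 ± 59.0 against 1.22 ± 0.912 CPM, log2 change 8.24), Faa, fumarylacetoacetase (138 ± 5.44 against 4.42 ± 0.927 CPM), E(spl)m7-HLH, a Notch target (56.0 ± 19.0 against 1.15 ± 0.364 CPM), and Fst, a gene of the cold response (142 ± 184 against 1.71 ± 1.92 CPM). CG34105 reached 38.6 ± 36.1 CPM and was at or below 1 read in each Canton-S library, so no fold is given. Beside Snap25, Ilp2 and Pdf, the largest falls were those of dpr21, an immunoglobulin-domain protein (log2 change -5.02), the transcription factor FoxP (-5.01), Hs3st-B, a heparan sulfate sulfotransferase (-4.94), the methyltransferase Setd3 (-4.71) and the peptide gene Orcokinin (-4.32). Of the 6259 genes 54.9% were higher, and 41.3% of the 6428 genes called after quantile normalization, which moved the median log2 change of all genes from 0.07 to -0.11.

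**Figure D2:**
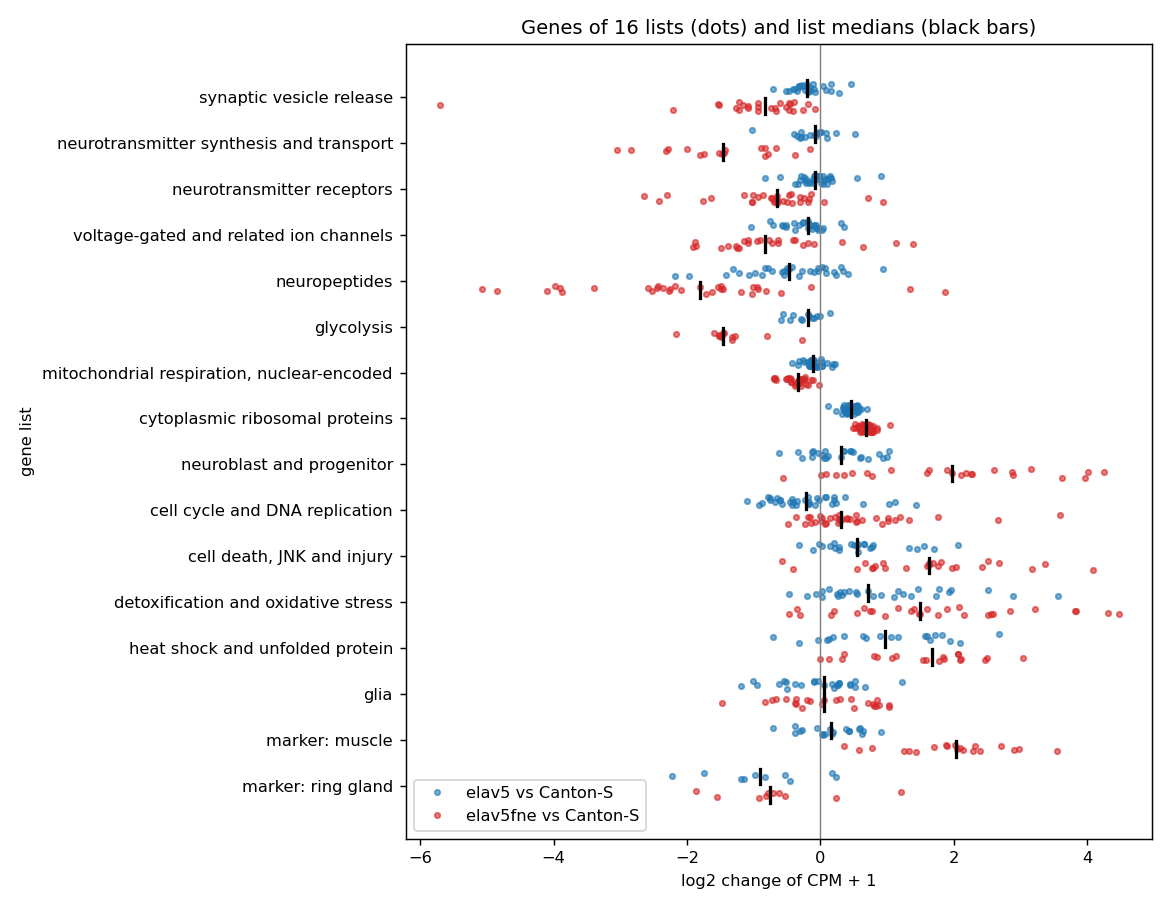
log2 change of CPM + 1 against Canton-S for each measured gene of 16 lists, as blue dots for the single mutant and red dots for the double mutant, with black bars at the list medians. The synaptic vesicle list had a median of -0.83 in the double and -0.20 in the single mutant, the neuropeptide list -1.80 and -0.47, and the neuroblast list 1.97 and 0.31.

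The second comparison set the single mutant, which lacks elav, against Canton-S. Of the 42 ribosomal protein genes 35 rose and none fell (41 adjusted over the list alone), by a median of 0.45 on the log2 scale, or 0.26 without single mutant replicate 2 (adjusted p = 3.2e-16, and adjusted p = 0.73 with an estimated correlation). Of 33 neuropeptide genes 15 fell and none rose (16 fell and 1 rose adjusted over the list alone, median -0.47), Pdf from 43.3 ± 4.33 CPM in Canton-S (n = 3) to 8.89 ± 2.49 CPM (n = 2). The neuropeptide list had an adjusted p = 0.0019 and an adjusted p = 0.73 with an estimated correlation, and its call was lost without single mutant replicate 1 (adjusted p = 0.067). The transcript of elav fell by 4.36 on the log2 scale (SE 0.13, adjusted p = 9.7e-06), fne had a log2 difference of 0.02 (SE 0.15, adjusted p = 0.93) and Rbp9 one of 0.61 (SE 0.33, adjusted p = 0.22).

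The ribosomal list had a median CPM of 650, 716 and 668 in Canton-S and of 805 and 1025 in the single mutant, and without single mutant replicate 2 and double mutant replicate 3 together, 22 of its genes rose. The detoxification list had 12 of 29 genes higher and none lower (13 and 1 adjusted over the list alone, median 0.72), with GstD2 at 21.6 ± 9.60 against 0.828 ± 0.180 CPM and GstE1 at 63.2 ± 14.4 against 10.5 ± 3.54 CPM. In the cell death, JNK and injury list 8 of 24 genes rose and none fell (13 and 1 adjusted over the list alone, median 0.56), including the death genes grim (7.86 ± 0.277 against 1.13 ± 0.184 CPM), skl (10.2 ± 0.187 against 2.50 ± 0.808 CPM) and rpr (7.79 ± 0.0935 against 2.10 ± 0.926 CPM). These lists had adjusted p = 2.1e-06 and 6.2e-06, and both an adjusted p = 0.57 with an estimated correlation. Of 25 neuroblast genes 5 rose and none fell, also adjusted over the list alone (median 0.31), with wor, a Snail-type factor of neuroblasts, higher by 1.03 on the log2 scale. Of 46 axon guidance genes 6 rose and 1 fell (3 and 0 adjusted over the list alone), NetA, a netrin, at 50.9 ± 4.59 against 34.3 ± 1.83 CPM. In the heat shock list the only member that passed, Gp93, fell (78.3 ± 1.44 against 130 ± 26.7 CPM), none passed when adjusted over the list alone, and the median was 0.97. The neuroblast, axon guidance and heat shock lists had adjusted p = 0.0068, 0.032 and 0.0088, and adjusted p = 0.73, 0.96 and 0.80 with an estimated correlation. These 3 calls changed when libraries were left out. The heat shock list had a median CPM of 347 in single mutant replicate 2 against 151 in replicate 1 and 59.6 to 161 in Canton-S, and without replicate 2 its call was lost (median 0.43, adjusted p = 0.24). Its median was 1.57 without replicate 1 and 0.53 without Canton-S replicate 1. Without single mutant replicate 1 the neuroblast and axon guidance calls were lost (medians 0.20 and -0.03, adjusted p = 0.11 and 0.87), and the latter also without Canton-S replicate 2 or 3 (adjusted p = 0.12 and 0.057). Without double mutant replicate 3, 12 axon guidance genes rose (adjusted p = 0.012). Without single mutant replicate 2 as well, 18 axon guidance genes rose and none fell (median 0.22, adjusted p = 2.5e-07), and 9 neuroblast genes rose (adjusted p = 2.2e-04).

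Some lists of neuronal function and of RNA processing were called lower in the single mutant. Not called were neurotransmitter synthesis and transport (4 of 18 genes lower and 1 higher), receptors (2 of 33 each way) and peptide processing (2 of 11 higher and none lower). These were the same counts as adjusted over the list alone, with adjusted p = 0.34, 0.71 and 0.87. Of 26 synaptic vesicle genes 7 fell and none rose, also adjusted over the list alone (median -0.20), among them Rop (731 ± 1.91 against 957 ± 20.7 CPM) and Syx1A (596 ± 17.1 against 757 ± 9.93 CPM). Of 26 ion channel genes 7 fell and none rose (9 fell adjusted over the list alone, median -0.18), with Hk, a potassium channel subunit, at 85.8 ± 16.8 against 176 ± 4.49 CPM. Of 28 genes with neural-extended 3' UTRs 8 fell and none rose (12 fell adjusted over the list alone), including elav itself, mei-P26 (495 ± 35.6 against 934 ± 50.7 CPM) and fru, the sex determination factor (16.7 ± 4.42 against 46.4 ± 3.12 CPM). Of 17 factors of 3' end processing 7 fell and none rose (9 fell adjusted over the list alone), with CstF50 at 6.19 ± 0.0485 against 13.8 ± 2.19 CPM. Neuronal RNA-binding protein genes had 5 of 25 lower and 1 higher (8 and 1 adjusted over the list alone). The deleted gene elav is among those lower, and the list was not tested without it. The synaptic, channel, extended 3' UTR, 3' end and RNA-binding lists had adjusted p = 0.032, 0.0053, 0.00051, 0.0047 and 0.026, and adjusted p = 0.87, 0.73, 0.73, 0.57 and 0.73 with an estimated correlation. Without single mutant replicate 2 the synaptic, channel and RNA-binding calls were lost (adjusted p = 0.087, 0.11 and 0.094), with a channel median of -0.09 (-0.32 without replicate 1), and the synaptic call also without Canton-S replicate 1 or 3 (adjusted p = 0.074 and 0.057).

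The ecdysone response, ring gland, glycolysis and hemocyte lists were called lower in the single mutant, and the respiration list, with 1 of 31 genes lower, was not (adjusted p = 0.31). Of 18 ecdysone response genes 6 fell and none rose (8 fell adjusted over the list alone, median -0.30), with Eip71CD at 9.65 ± 1.33 against 144 ± 33.6 CPM. Of 10 ring gland genes 6 fell and none rose (8 fell adjusted over the list alone, median -0.91), with spok at 2.47 ± 0.698 and sad at 1.24 ± 1.03 CPM against 15.4 ± 4.15 and 6.21 ± 1.63 CPM. Of 13 glycolysis genes 4 fell and none rose (5 fell adjusted over the list alone, median -0.19), Hex-A, hexokinase, from 624 ± 24.8 to 422 ± 3.55 CPM. Of 18 hemocyte genes 2 fell and none rose (9 fell adjusted over the list alone, median -0.72), and the collagen gene Col4a1, made by hemocytes and fat body, stood at 95.9 ± 118 against 397 ± 83.0 CPM (adjusted p = 0.066). The share of reads in the hemocyte list was 0.0992% in single mutant replicate 1 and 0.0240% in replicate 2, and between 0.149% and 0.195% in Canton-S. These lists had adjusted p = 0.0081, 0.0037, 0.032 and 0.0036, and adjusted p = 0.57, 0.73, 0.73 and 0.73 with an estimated correlation. The glycolysis call was lost without Canton-S replicate 1 or 3 or single mutant replicate 1 (adjusted p = 0.056, 0.065 and 0.29), and the hemocyte call without single mutant replicate 2 (median -0.31, adjusted p = 0.17). Without that replicate the ring gland median was -0.55 and the glycolysis median -0.30, and without replicate 1 the hemocyte and glycolysis medians were -1.32 and -0.08. Of the 20 muscle genes none passed the test, and the single mutant libraries differed (median CPM 94.9 and 38.7). Without single mutant replicate 2 the muscle, trachea and cuticle, and eye disc lists were called higher and the respiration list lower (medians 0.87, 0.73, 0.34 and -0.21, adjusted p = 0.0083, 0.044, 0.0085 and 0.0038). In all, 17 lists were not called, and among them the median and the direction of the test differed in sign for the ELAV/Hu family, peptide processing, gut and salivary gland lists, and the median and mean for the glia and Hox lists. The receptor list, with a median of -0.08 and 2 genes each way, turned in sign with median-ratio scaling, and 3 cell cycle genes rose and 9 fell (5 and 13 adjusted over the list alone, adjusted p = 0.28).

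In all, 2124 of 10575 genes passed the test between the single mutant and Canton-S, 877 higher and 1247 lower, with 273 and 209 of them changed at least 2-fold. edgeR called 1979 genes and DESeq2 2717. The metallothionein genes MtnB and MtnD, which bind heavy metals, led the rises at 26.1 ± 13.5 and 22.8 ± 10.9 CPM, and no Canton-S library had more than 2 reads of either. The rises went on with GstD2, Pepck2, a carboxykinase of gluconeogenesis (25.7 ± 1.88 against 1.45 ± 0.684 CPM), CG32581, Ppi1, ChLD3 and Arc1, a capsid-forming neuronal gene (289 ± 5.84 against 36.7 ± 7.10 CPM). After elav, the largest falls were those of CG10936, the lysosomal gene Cln3 (0.662 ± 0.429 against 24.8 ± 3.07 CPM), Eip71CD, CG11300, the cytochrome P450 gene Cyp6w1, Orcokinin and sn, the fascin that bundles actin (10.0 ± 0.832 against 100.3 ± 7.52 CPM). The count was 904 without Canton-S replicate 1 and 1053 without Canton-S replicate 2. Of these, 891 and 1019 were among the 2124 in the same direction, and none of the 2124 that were tested changed sign. Fewer libraries lower the power of the test, so the drop does not show that the calls rested on 1 library. Of the 2124 genes 41.3% were higher, against 55.4% of 1982 genes with median-ratio scaling and 52.4% of the DESeq2 calls.

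The third comparison tested the difference between the mutants, which differ in fne and, as separate lines, may differ elsewhere, as in w. Of 33 neuropeptide genes 28 fell and 2 rose and of 18 neurotransmitter synthesis and transport genes 17 fell and none rose, the same counts as adjusted over each list alone. Proc, the proctolin precursor, stood at 41.1 ± 6.64 CPM in the double mutant (n = 3) and 334 ± 49.3 CPM in the single mutant (n = 2), and the dopamine transporter DAT at 35.6 ± 6.63 and 174 ± 4.36 CPM. Of 25 neuroblast genes 21 rose and 1 fell, also adjusted over the list alone, with ase at 207 ± 23.3 against 24.4 ± 3.16 CPM. The transcript of fne fell by 2.79 (SE 0.15, adjusted p = 1.2e-05) on the log2 scale, that of elav rose by 0.94 (SE 0.13, adjusted p = 7.7e-04), and Rbp9 differed by 0.44 (SE 0.33, adjusted p = 0.30).

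Between the mutants, 19 of 26 synaptic vesicle genes fell (20 adjusted over the list alone, median -0.69), 25 of 33 receptors fell and 2 rose (27 and 2, median -0.65), 14 of 26 ion channel genes fell and 2 rose (the same adjusted over the list alone, median -0.41), and 6 of 11 peptide processing genes fell (the same, median -0.33). The neuropeptide, synthesis, synaptic, receptor, channel and processing lists had adjusted p = 5.9e-14, 9.9e-13, 2.8e-10, 1.7e-10, 1.7e-05 and 0.0010, and adjusted p = 0.39, 0.43, 0.44, 0.45, 0.55 and 0.43 with an estimated correlation. Glycolysis genes fell in 12 of 13 cases, also adjusted over the list alone, with Tpi at 412 ± 36.6 against 1132 ± 72.2 CPM, and 13 of 31 respiration genes fell (14 adjusted over the list alone). Those lists had adjusted p = 4.7e-10 and 8.2e-06, and adjusted p = 0.39 and 0.65 with an estimated correlation. Of 18 ecdysone response genes 8 fell and 4 rose, Hr38, a nuclear receptor gene, from 53.9 ± 16.1 to 9.46 ± 1.22 CPM, and of 10 Hox and segment identity genes 5 fell, Ubx from 154 ± 23.7 to 92.9 ± 17.1 CPM. Both had the same counts adjusted over the list alone, adjusted p = 0.048 and 0.024, and adjusted p = 0.43 and 0.73 with an estimated correlation. The Hox call was lost without double mutant replicate 3 (median -0.19, adjusted p = 0.056) or single mutant replicate 1 (adjusted p = 0.22). The channel median was -0.25 without single mutant replicate 1, and the processing median -0.22 without double mutant replicate 3. The ecdysone call was lost without any 1 of 6 libraries, the 3 of Canton-S, single mutant replicate 1 and double mutant replicates 1 and 2, with adjusted p from 0.050 to 0.12.

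Among lists higher in the double than in the single mutant, the neuroblast list had a median of 1.82, and 22 of 36 cell cycle genes rose and none fell (23 adjusted over the list alone, median 0.70), with CycA, cyclin A, at 107 ± 10.7 against 34.7 ± 7.06 CPM. Of 24 cell death, JNK and injury genes 17 rose and 1 fell (18 and 1 adjusted over the list alone), with egr, the TNF ligand of the fly, at 137 ± 8.90 against 39.9 ± 1.59 CPM. Of 15 immunity genes 9 rose (10 adjusted over the list alone), and of 29 detoxification genes 15 rose and 2 fell (15 and 3 adjusted over the list alone), the latter including the glucuronosyltransferase Ugt35B1 at 0.943 ± 0.628 against 7.19 ± 1.69 CPM. The neuroblast, cell cycle, cell death, immunity and detoxification lists had adjusted p = 2.8e-07, 1.1e-04, 7.0e-04, 0.0056 and 0.016, and adjusted p = 0.43, 0.64, 0.45, 0.64 and 0.64 with an estimated correlation. Of 42 ribosomal protein genes 8 rose (7 adjusted over the list alone, median 0.24, adjusted p = 0.016, and adjusted p = 0.94 with an estimated correlation), and 40 rose when single mutant replicate 2 and double mutant replicate 3 were left out (median 0.43). Of 8 germline genes 3 rose, also adjusted over the list alone, with vas, an RNA helicase of germ cells, at 30.1 ± 0.933 against 4.01 ± 0.167 CPM (list adjusted p = 0.031, and adjusted p = 0.43 with an estimated correlation). The ribosomal and germline calls were lost without single mutant replicate 1 (adjusted p = 0.93, median 0.04, and adjusted p = 0.072) or double mutant replicate 1 (adjusted p = 0.062 and 0.050).

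Non-neural markers also differed between the mutants. Of 20 muscle genes 8 rose (11 adjusted over the list alone, median 1.76), of 18 hemocyte genes 12 rose and 2 fell (14 and 2 adjusted over the list alone, median 1.89), of 15 trachea and cuticle genes 5 rose (5 adjusted over the list alone, median 1.47) and of 25 gut genes 5 rose (2 adjusted over the list alone, median 2.46). The laminin genes LanB1 and LanB2, of the extracellular matrix, stood at 423 ± 65.9 and 303 ± 39.6 CPM against 65.6 ± 42.9 and 48.3 ± 31.1 CPM. These lists had adjusted p = 0.0025, 0.027, 0.048 and 0.018, and adjusted p = 0.79, 0.83, 0.83 and 0.87 with an estimated correlation. Without both single mutant replicate 2 and double mutant replicate 3, only 5, 9, 2 and 3 genes of them rose, the medians were 0.50, 0.95, 0.25 and 1.02, and the trachea and cuticle call was lost (adjusted p = 0.61). That call was also lost without any 1 of 5 libraries, Canton-S replicate 1 or 3, single mutant replicate 2, or double mutant replicate 2 or 3 (adjusted p = 0.054, 0.051, 0.47, 0.053 and 0.056), and the gut call without single mutant replicate 1 (adjusted p = 0.085). The heat shock list was not called, but was called higher without single mutant replicate 2 (median 0.80, adjusted p = 0.033), and the axon guidance list lower (median -0.23, adjusted p = 0.0053). In all, 12 lists were not called, and among these the ELAV/Hu family, glia, neuronal RNA-binding, extended 3' UTR, 3' end and ring gland lists had medians above 0 and a test direction below 0.

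Between the mutants 4593 of 10575 genes passed the test, 2830 higher and 1763 lower in the double mutant, with 1239 and 531 of them changed at least 2-fold. edgeR called 4313 genes and DESeq2 4904. Beside w, the largest rises with a gene name included those of Nlg1 (log2 change 4.49), Adgf-A, an adenosine deaminase growth factor (89.7 ± 2.88 against 3.12 ± 0.836 CPM), the kinetochore gene Kmn1, meso18E and wntD, a Wnt ligand (27.0 ± 8.73 against 0.496 ± 0.230 CPM). The largest falls were those of dpr21, Snap25 (4.69 ± 4.26 against 155 ± 34.1 CPM), Hs3st-B, FoxP, Setd3, Gpb5, a glycoprotein hormone subunit, Ilp2 and CG14431. Of these calls 61.6% were higher, against 43.0% after quantile normalization and 50.4% with edgeR, and quantile normalization moved the median log2 change of all genes from 0.14 to -0.07.

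The changes of both mutants against the shared Canton-S libraries were then set side by side. Of the genes tested, 673 rose in both mutants and 839 fell in both, where independent lists of these sizes would share 285 and 333. These shared calls, 1512 in all, were 638 without Canton-S replicate 1 and 1792 without double mutant replicate 3. Unchanged groups simulated against the same controls shared 0.01 calls on average over 100 draws. With no change simulated, few genes are called at all, so this count cannot show what shared controls add to real changes. Another 131 genes passed in both mutants in opposite directions, fewer than independent lists of these sizes would share. Across genes, which are not independent replicates, the log2 changes had Pearson's r = 0.523 and Spearman's rho = 0.530, beside a simulated r of 0.444 for unchanged groups. Their covariance was 0.307 against a simulated 0.0322, a difference of 0.275. Signs were the same for 69.4% of genes against 64.7% in the simulation. The 3 control libraries cannot give each mutant at least 2 of its own. In a fit chosen after the result was seen, 1 Canton-S library served 1 mutant and the other 2 libraries the other mutant. Over the 6 such divisions the covariance averaged 0.288 (0.272 to 0.309) and r averaged 0.468 (0.430 to 0.517). The genes called in the same direction averaged 480 (144 to 807), with fewer controls behind each call. Part of the excess over independent lists may come from the shared controls. A difference in line or in the sex of the larvae that both mutants share would add to the agreement. Dividing the controls does not remove such a difference, and it was not tested.

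**Figure D3:**
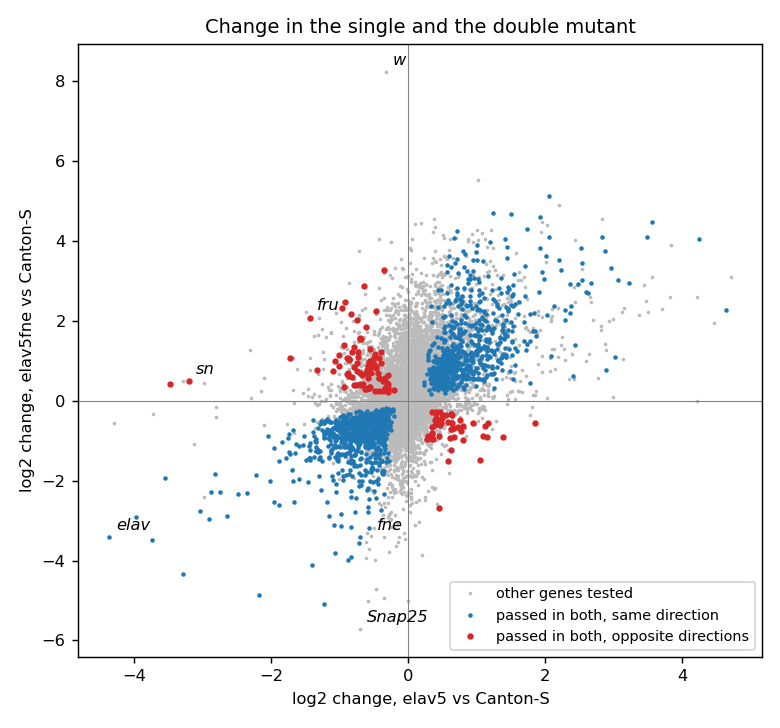
log2 change of each tested gene in the single mutant (horizontal axis) and the double mutant (vertical axis), both against Canton-S, with genes that passed the test in both in the same direction in blue, those in opposite directions in red and all others in grey. The blue points number 1512 and the red points 131, and w, with a log2 change of 8.24 in the double mutant, stands apart at the top.

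Transcripts tied to sex differed between both mutants and Canton-S. The dosage compensation RNA lncRNA:roX1 stood at 1450 ± 38.0 CPM in Canton-S, 3411 ± 599 in the single and 3475 ± 246 in the double mutant, and lncRNA:roX2 at 175 ± 5.40, 602 ± 231 and 473 ± 27.8 CPM. Both rose in the single (adjusted p = 0.0020 and 0.0026) and in the double mutant (adjusted p = 6.6e-05 and 3.1e-04). msl-2, the male-specific subunit of the complex, rose from 45.3 ± 2.42 to 75.4 ± 2.66 and 79.0 ± 4.11 CPM, and Sxl, the female-determining gene, fell by 0.81 in the single and by 0.98 in the double mutant on the log2 scale. tra, the next gene of the female pathway, passed in neither mutant against Canton-S (adjusted p = 0.19 and 0.071). The sex of the larvae is not in the labels.

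**Figure D4:**
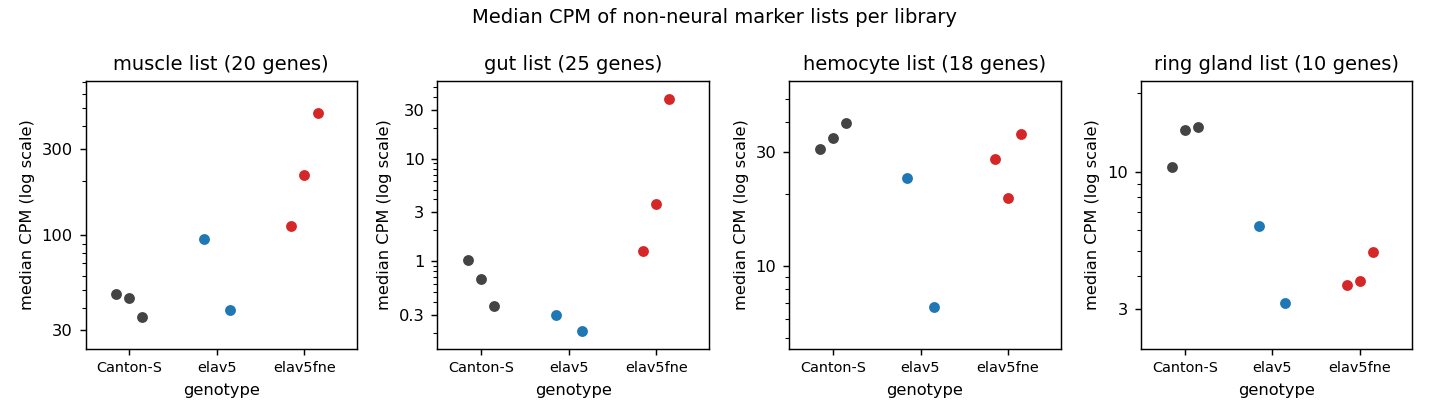
Median CPM, on log axes, of the measured genes of 4 marker lists in each library, as dots by genotype. The muscle list stood at 471 CPM in double mutant replicate 3 against 113 and 214 CPM in the other double mutant libraries, the gut list at 38.2 CPM in that library, the hemocyte list at 6.77 CPM in single mutant replicate 2, and the ring gland list between 3.17 and 6.23 CPM in the mutant libraries.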

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

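The tests on Y-linked genes and on regroupings of the libraries were chosen before their results were seen, and all other tests of this part were chosen after. The 2 mutants differed in direction for 131 genes that passed in both, beside 1512 with the same direction. Independent lists of these sizes would share more genes in opposite directions, so the 131 are no sign of general disagreement. The log2 change in the double mutant minus that in the single mutant, which was tested as the difference between the mutants, was 3.70 for sn, 3.52 for fru, 2.29 for Gp93, 2.05 for Hr4, 1.499 for btl, the FGF receptor of tracheal cells, and 0.91 for ogre, an innexin. No explanation was tested for these genes.

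lncRNA:roX1, lncRNA:roX2 and msl-2 were higher and Sxl was lower in both mutants than in Canton-S, the direction of a larger share of males. Y-linked genes could not decide it, as their mean over the 8 libraries was 0.0151 CPM per gene, below the floor of 3 reads. Their sum was 1.57 to 1.60 CPM in Canton-S, lower in the single (0.965 and 1.05) and higher in the double mutant (1.99 to 2.47). If both proteins acted on these RNAs together, lncRNA:roX1 would differ between the mutants, and its log2 difference was 0.036 (SE 0.131). Equal levels in both mutants would follow from a sex difference that both share, or from an effect of elav loss alone. Neither test decides, since sex is not in the labels and a difference in sex between the groups would go with genotype. A difference in the sex of the larvae, an effect of ELAV loss on these transcripts and a difference in strain stay open.

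Muscle, gut and cuticle markers were higher in the double mutant. In replicate 3 the gut list had a median log2 ratio of 2.501 to replicates 1 and 2, and muscle and cuticle 1.331 and 1.092, while the fat body list had -0.059. These values prompted the idea of non-neural tissue carried into that library, so they are no independent test of it, and it stays open. Replicate 3 alone does not explain the muscle list, as 15 of its genes still rose without it, and neither does depth, as the library with the most reads had a muscle median of 35.6 CPM. More adhering tissue in all double mutant dissections and a change within the mutant CNS stay open, and were not tested.

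Most genes of the synaptic vesicle list were lower in the double mutant. Dilution that acts equally on every gene of the list, as the whole cause, would move them alike. Only 26.9% of the synaptic vesicle genes (7 of 26) lay within 2 SE of the list median. Their log2 changes ran from -5.711 for Snap25 to -0.081 for Syt4. This argues only against equal dilution as the whole cause. A lower share of neurons need not move the genes equally, as other cells may express some of them. Neuron types may also be lost unequally, so the test cannot decide on a loss of neurons. The choice among the scalings used did not produce the fall, as the list median was at most -0.821 under quantile normalization and median-ratio scaling. Both moved the median log2 change of all genes little, from 0.07 to -0.11 and 0.07. Neither scaling measures a change in the total amount of RNA, which stays open. A loss of neurons as the whole cause stays open. A partial loss of neurons beside regulation of single genes, and a delay in development, also stay open and were not tested.

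Regroupings of the 6 Canton-S and double mutant libraries make only 10 splits, too few for a share under 0.05. For the 6259 genes called, 1 split gave as many (the real one) and the highest other gave 0. For the 22 lists called, 2 splits gave as many and the highest other gave 22. Every split other than the real one called at least 11 lists, though it called 0 genes. Each group of those splits held 2 libraries of 1 genotype and 1 of the other, so part of the genotype difference stayed in them. Mixed groups also widen the spread within a group, which lowers the gene calls. Their list calls therefore cannot show how many lists would be called without a difference. A list call at the preset correlation stays weak evidence, as camera kept none with an estimated correlation.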

How the results depend on the processing

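All tests in this part were planned except the fit without both outlying libraries (single mutant replicate 2 and double mutant replicate 3) and that with separate controls, which were chosen after the result was seen. Of the main counts and the agreement, 148 values stayed within a tolerance, and 17 moved further. The tolerance was 1.5 times the main count, or 0.0422 for r (the SD of r with 1 library left out). For r that tolerance comes from the left-out fits that it also judges, so their staying within it is no independent sign of stability. A count has no direction, so none of these counts could reverse. With quantile normalization the share of calls that were higher went from 54.9% to 41.3% in the double mutant against Canton-S. Between the mutants that share went from 61.6% to 43.0%. With median-ratio scaling it went from 41.3% to 55.4% in the single mutant against Canton-S. Quantile normalization changed the sign of 44, 1 and 2 of the main calls in the 3 comparisons. For single genes 7866 values were the same, 78 gained and 258 lost the threshold, and for single lists 1902, 38 and 139. The cause of these moves was not tested.

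The genes changed in the single mutant, 2124, fell to 932 with the replicate number as a block, and with 1 library left out ranged from 806 (without single mutant replicate 2) to 2589 (without double mutant replicate 3). Genes called in the same direction in both mutants, 1512, fell to 714 with the block and ranged from 638 (without Canton-S replicate 1) to 1792 (without double mutant replicate 3). With separate controls they averaged 480. The agreement of the mutants, r = 0.523, was 0.468 with separate controls, 0.579 with edgeR, 0.589 with DESeq2 and 0.569 without both outlying libraries, and ranged from 0.417 (without single mutant replicate 1) to 0.559 (without single mutant replicate 2). The replicate numbers did not pair the samples. Where 1 single mutant library is left, it is assumed to vary like the other groups.

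Lists called, 22, 16 and 21 in the 3 comparisons, became 0, 0 and 0 when camera estimated the correlation. With fry they were 26, 12 and 16. Set tests were not run with DESeq2. Genes changed in the double mutant against Canton-S ranged from 5228 to 6393 with 1 library left out, and between the mutants from 3361 to 4355. Depth sets the floor of 3 reads, 0.0788 to 0.0999 CPM. Spread between replicates went beyond counting error, with a mean chi-square per degree of freedom of 26.2 to 132. The median over genes was lower, 2.73 to 8.59. The self-test used 1 depth and 1 group size per comparison, so it does not separate depth from the number and spread of replicates.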

Other observations

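All of the genes in this part were chosen after their values were seen, with no test beyond those of the comparisons. Of 11 measured genes of the E(spl) complex, which holds targets of Notch, 11 rose in the double mutant against Canton-S (median log2 change 3.86), 2 in the single mutant (median 0.83) and 11 between the mutants (median 3.01).

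The transcription factor gene ttk, a repressor of neuronal fate, stood at 465 CPM on average in the double mutant, 27.4 in Canton-S and 28.4 in the single mutant. Between Canton-S and the single mutant, 4 genes went from the floor to expression (lncRNA:CR46123, lncRNA:CR45900, MtnB and MtnD), and 3 did so in the double mutant (lncRNA:CR45900, lncRNA:CR44953 and CG34105).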
